A study of Mus musculus with 4 samples.

How the data were processed

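RNA from cultured mouse embryonic fibroblasts that lack Men1 was hybridised to 4 Affymetrix arrays. Per the labels, 2 arrays held RNA from cells given Men1 back and 2 held RNA from cells given vector. Also per the labels' protocols, the cells grew in medium with 10% serum, were seeded at 70% density, and were harvested after 24 h. The RNA was amplified and labelled with biotin. The protocol describes priming with random as well as poly(T) oligomers and labelling of cDNA ends, whereas the probe sets are of an earlier Affymetrix design made for poly(T)-primed targets. The labels do not resolve this, so it is not known here how each signal depends on the part of the transcript that was labelled.

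The deposited values are linear probe set intensity, made by the authors with Affymetrix Expression Console and MAS5 per the submitters' processing notes. Versions and the target of the scaling were not given in the sources used here. The mean signal after trimming 2% at each end was 150.08, 150.08, 150.08 and 150.07 on the arrays, so each array had been scaled as a whole. Scaling of this kind cannot show a change in total RNA per cell. Median signals lay between 50 and 62.4. The 75th percentiles lay between 186.2 and 195.1, a range of 0.067 on the log2 scale. This was within the 0.1 set before the data were examined, so no further normalization was applied.

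The table held 12488 probe sets. The 66 control probe sets of the array were left out, although the plan made before the data were examined named all probe sets, and 12422 were tested. Of these, 10833 had 1 gene symbol in the platform annotation, 396 had several and 1193 were unnamed, so that 8251 genes were named. No gene was named from a probe set with several symbols. Gene IDs of 10817 single-gene probe sets were found in a mouse gene table (GRCm38.p6), which was used for names only. No coordinates are given because no build was named.

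Signals were analysed as log2(signal + 16). Differences are Men1-complemented minus vector, and on this scale they understate the fold of dim probe sets. Each probe set was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom and 2.87 prior degrees of freedom. The number of arrays limits the precision, and the median standard error (SE) of a difference was 0.22. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

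Detection calls were not used here. Signals were instead set beside the 19 control probe sets for which no RNA had been spiked in, whose highest signal was 25.9 and 27.4 on the Men1-complemented arrays and 15.9 and 20 on the vector arrays. A probe set that did not exceed this on either array of a group is called at control level there. Its fold is given as "at least", from the mean log2(signal + 16) of the brighter group over that of the higher of the control and the dim signal.

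Membership of 30 gene lists was fixed before the data were examined. They cover genes reported as menin targets, the menin complex, Hox and Meis genes, cyclin-dependent kinase inhibitors with p53 targets, the cell cycle, replication histones, collagens, matrix remodelling, and the TGF-beta and BMP, hedgehog and Wnt pathways. Others cover growth factors, interferon response, inflammation, immediate-early genes, cholesterol and fatty acid synthesis, glycolysis with hypoxia, the unfolded protein response with amino acid metabolism, NRF2 targets, cytosolic ribosome and oxidative phosphorylation. The last lists hold markers of fibroblasts, smooth muscle, adipocytes, bone and cartilage, skeletal muscle, epithelium, endothelium, blood cells and neural cells. Each gene was represented by its probe set with the highest mean. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 30 lists, beside camera with an estimated correlation and fry. At the preset correlation the p takes genes as its units and does not measure the spread between arrays. With an estimated correlation camera takes its p from the residual degrees of freedom, 2 in the main fit. A list can then hardly pass after adjustment, and still less in fits that leave fewer. The median of a list was also ranked among 10000 random lists of the same size and matched signal.

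Genes were named by a rule fixed before the data were examined. It took Men1, all measured members of the list of reported menin targets, up to 4 members of each list by smallest p, and up to 12 genes in each direction among those past the threshold. Where fewer passed, places were filled with genes at an unadjusted p under 0.01 whose groups did not overlap, by size of the difference. Not all list members that the rule takes are named below. Those named from a list are not always the ones with the smallest p. Further genes of the cholesterol and fatty acid list, and the genes named for replicate number, were chosen after their values were seen.

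The procedure was tested on simulated data for the comparison of 2 against 2 arrays over 12422 probe sets, with 20 simulations of 200 changed probe sets. It recovered 28.8% of probe sets changed by 1 on the log2 scale, 97.2% of those changed by 2 and 99.8% of those changed by 3. An unadjusted p under 0.05 was given to 4.92% of unchanged probe sets. A mean of 11.75 unchanged probe sets per simulation passed the adjusted threshold. In 20 of 20 simulations a shift of -0.57 in the cholesterol and fatty acid list was found at the preset correlation. With an estimated correlation it was found in 0 after adjustment and in 20 at an unadjusted p under 0.05, and with fry in 7. Among 560 tests of unshifted lists, 1 passed. The simulated noise was independent between genes and between arrays, with no difference by replicate number. In the data only 233 of 12422 probe sets had an unadjusted p under 0.05, so the simulated rates may not hold for these arrays.

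Alternatives set before the data were examined were quantile normalization, leaving out the dimmest 30% of probe sets, a variance trend with robust priors, the replicate number as a block, a pseudocount of 1, the mean of all probe sets of a gene, other thresholds, and leaving out each array in turn. Inclusion of the control probe sets, and the cholesterol and fatty acid list without its members that are not synthesis enzymes, were added after the data were seen.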

Results

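Gene expression was measured on 4 arrays of mouse embryonic fibroblasts without Men1, the gene of menin, a nuclear scaffold protein that works with histone methyltransferases. Of these, 2 arrays held cells given Men1 and 2 held cells given vector. The series asked which genes lie downstream of menin. Groups below are named as labelled.

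The single Men1 probe set read 18.8 and 22.5 on the Men1-complemented arrays and 18.1 and 29.5 on the vector arrays. The log2 difference was -0.11 with an SE of 0.22, and the limma adjusted p was 1. Both Men1-complemented signals were at control level. Where this probe set lies relative to the deleted and the introduced sequence is not known here, so it checks the labels in neither direction.

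Genes of cholesterol synthesis were lower in the Men1-complemented fibroblasts. Idi1, which makes the isoprenoid unit dimethylallyl diphosphate, had a mean signal of 129.55 ± 2.19 (SD, n = 2) against 312.9 ± 14.4 (SD, n = 2) with vector. Fdps, farnesyl diphosphate synthase, stood at 798 ± 10.5 against 1588 ± 39.1. Of the 28 measured genes of the cholesterol and fatty acid synthesis list, 27 were lower and 1 was higher, with a median log2 difference of -0.57. The list also holds 4 measured members that are not synthesis enzymes, the sterol efflux transporters Abca1 and Abcg1 and the regulators Srebf1 and Insig1, and all of the other 24 were lower. The list passed the threshold in camera at the preset correlation (adjusted p = 1.57e-22). That p takes genes as its units, and these genes are regulated together and were measured on the same 4 arrays. Its size therefore does not measure the spread between arrays, where the 3 ways to divide them allow no permutation p below 0.333. The list did not pass with an estimated correlation (adjusted p = 0.227 and unadjusted p = 0.00758 with an estimated correlation), nor with fry (adjusted p = 0.0778). The estimated correlation was -0.015, below the preset 0.01, so a higher correlation between genes does not explain the larger p. That p rests on the 2 residual degrees of freedom. In the simulations a shift of -0.57 in this list passed in 0 of 20 this way after adjustment. Not passing with an estimated correlation therefore does not argue against a shift of this size.

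Within this list, 6 genes passed when adjusted over the list alone, and 0 passed over all probe sets. All 6 were lower. Besides Idi1 (log2 difference -1.18, SE 0.17) and Fdps (-0.98, SE 0.17), these were Lss, lanosterol synthase (-0.97, SE 0.19), and Msmo1, a methyl sterol oxidase (-0.95, SE 0.17). The others were Cyp51, the lanosterol demethylase (-0.85, SE 0.19), and Sqle, squalene epoxidase (-0.73, SE 0.18). Mean signals of Msmo1 were 162 ± 1.77 and 328 ± 15.3 (SD, n = 2 each), and those of Lss 113 ± 10.5 and 236 ± 22.3. A second Fdps probe set differed by -0.87, whereas a dim one differed by 0.24.

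**Figure D1:**
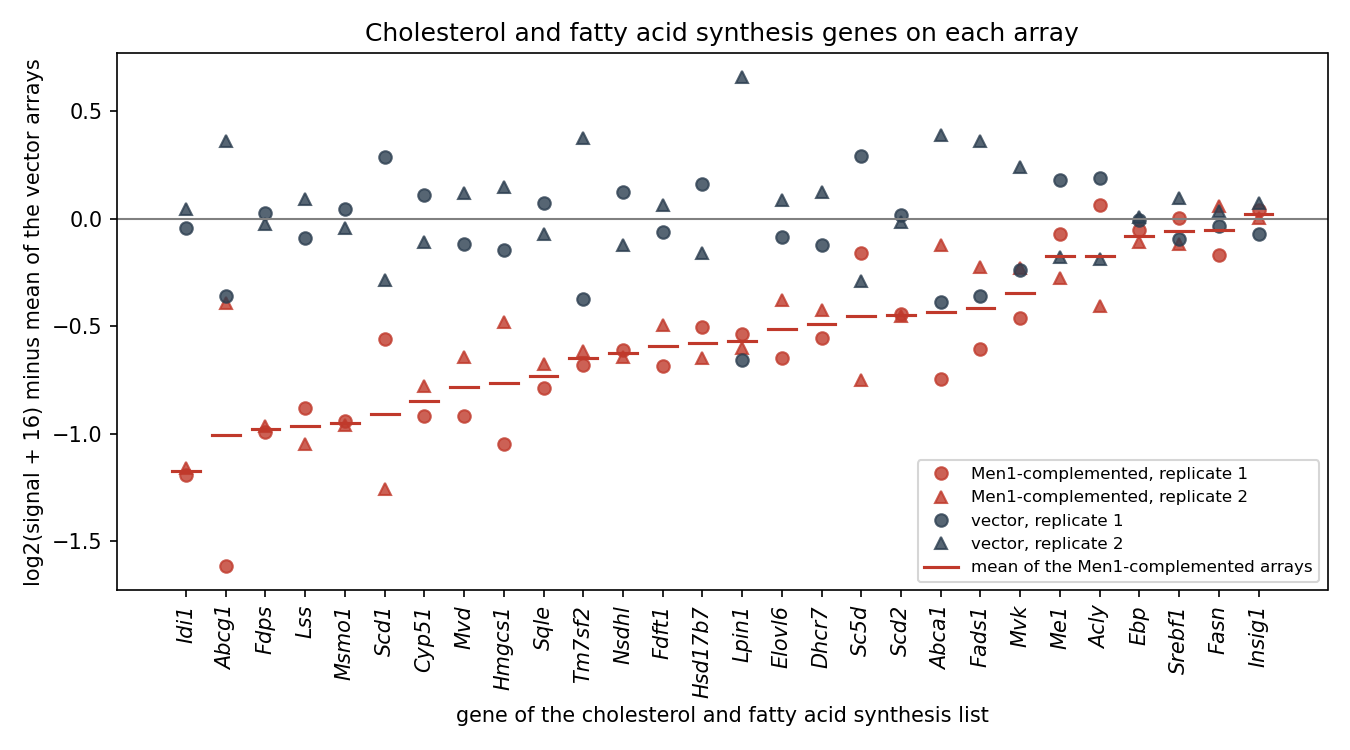
Log2(signal + 16) of the 28 measured genes of the cholesterol and fatty acid synthesis list on each of the 4 arrays, relative to the mean of the vector arrays, with genes ordered by the mean difference. Points are arrays and bars are means of the Men1-complemented arrays; 27 of the 28 bars lie below 0.

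Other members of the list did not pass when adjusted over it. Hmgcs1, which makes the precursor of mevalonate, differed by -0.76 (SE 0.27), Mvd by -0.78 (SE 0.20), Nsdhl by -0.63 (SE 0.19) and Fdft1, squalene synthase, by -0.59 (SE 0.18). Scd1 and Scd2, which desaturate stearoyl-CoA, differed by -0.91 (SE 0.33) and -0.45 (SE 0.17). Fasn, fatty acid synthase, differed by -0.05 (SE 0.18), Srebf1, a transcription factor of lipid synthesis, by -0.06 (SE 0.18) and Acly by -0.17 (SE 0.26). Abcg1 read 15.8 and 58.2 against 59.9 and 109.2 (SE of the log2 difference 0.48), and Abca1, at control level with Men1, read 11.4 and 26.2 against 19.2 and 44.2, which overlap. Insig1 was at control level in both groups. Groups did not overlap for 18 of the 28 genes, all lower, where chance gives 33.3% in both directions together. Median differences of the 4 pairs of arrays across groups, which share arrays and are not independent, ranged from -0.44 to -0.72, with 22 to 27 genes lower. Among 10000 random lists of matched signal the median was at percentile 0, as was that of oxidative phosphorylation (-0.10), while immediate-early genes (0.18) were at 100.

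The smallest adjusted p of the other 29 lists at the preset correlation was 0.173, and 0 of their genes passed when adjusted over their list alone.

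No probe set passed the limma threshold over all 12422, and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 233, 113 higher and 120 lower, where chance gives 621. Groups did not overlap for 22.1% of probe sets, where chance gives 33.3%. In both counts the groups differed less than chance gives for independent arrays, but without vector replicate 1 the first count was 1031, above the chance value. Both groups held an array of each replicate number, and division of the arrays by that number gave 1491 probe sets at an unadjusted p under 0.05. The fit counts this difference as spread within groups, so the low counts do not show that the groups were unusually alike. With replicate number as a block the count was 297, still below the chance value. The median absolute log2 difference was 0.196 between the Men1-complemented arrays and 0.306 between the vector arrays, and 0.189 to 0.257 across the groups.

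At an unadjusted p under 0.01 there were 29 probe sets, 13 higher and 16 lower, where chance gives 124. Among the genes chosen by size at this cut, none of which passed, 10 were higher with Men1. Foxk1, a forkhead transcription factor, read 86.8 and 72.8 against 12.5 and 20.1, a log2 difference of 1.57 (SE 0.21). Pacsin1 differed by 1.06 (SE 0.17) and Lbp, a lipopolysaccharide-binding protein, by 0.91 (SE 0.18). The vector signals of Foxk1 and of Lbp (18.1 and 19.8) lay near or below the highest controls of 15.9 and 20. The sizes of these differences are therefore uncertain. The vector arrays were at control level for the chosen probe sets of Erp29 (at least 1.62-fold), Pik3cd (at least 1.68-fold), Sars2 (at least 1.36-fold), Gtf3c4 (at least 1.62-fold), Tulp1 (at least 1.60-fold) and Rtkn (at least 1.64-fold). The chosen Nectin3 probe set was at control level in both groups, and its brighter one only with Men1. Of these 10 genes, 6 had other probe sets, and 0 of the 7 other probe sets separated the groups the same way. Brighter probe sets, above the controls on the vector arrays, differed by -0.11 for Erp29, -0.07 for Sars2, 0.0006 for Gtf3c4 and -0.11 for Rtkn. The other Pik3cd probe set, also above the controls there, differed by -0.12. These genes were therefore not at control level with vector.

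In the lower direction, 12 genes met the same rule, including Idi1, Fdps, Lss and Msmo1. Matk, a tyrosine kinase, read 38.3 and 48.8 against 109.3 and 86, a log2 difference of -0.93 (SE 0.21). Myog, the muscle transcription factor myogenin, differed by -0.87 (SE 0.20). With Men1 it read 23.7 and 28.1, near the highest controls of 25.9 and 27.4, so the size of this difference is uncertain. The Men1-complemented arrays were at control level for Wnt3 (at least 1.46-fold), Upf2 (at least 1.14-fold), Kif5a (at least 1.06-fold), Lmo2 (at least 1.20-fold), Adgrb1 (at least 1.28-fold) and Barx1 (at least 1.00-fold). A second probe set of Lmo2 also separated the groups. Those of Kif5a and Barx1 did not, but they were at control level in both groups and so decide nothing.

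Genes reported elsewhere as menin targets did not pass as a list (26 measured, 10 higher, 16 lower, median -0.10, camera adjusted p = 0.704). Of its members, Foxa2, Hoxa10, Hoxc6 and Fgf9 were at control level in both groups. Hoxa9, Meis2, Ptn and Pparg were at control level with Men1, as were Gli1, a hedgehog effector, and the cell cycle inhibitor Cdkn1b in both of its probe sets. None of these 6 gave a bound on the fold above 1. Gli1 read 7.4 and 4.9 with Men1 and 13.7 and 25.8 with vector, and the brighter Cdkn1b probe set read 15.6 and 22.2 against 15.6 and 20.3. The dimmer Cdkn1b probe set read 8.8 and 6.6 against 16.8 and 24.5, a log2 difference of -0.62 (SE 0.20) that did not pass (unadjusted p = 0.0269). Cdkn2c, another cell cycle inhibitor, differed by -0.09 (SE 0.28), Lox, lysyl oxidase, by -0.48 (SE 0.25) and Hoxc8 by -0.37 (SE 0.28). A second, dimmer Lox probe set differed by 0.25 (SE 0.26). Ptch1 differed by 0.21 (SE 0.18), Gli3 by 0.11, Ezh2 by 0.13, Bmi1 by 0.19, Inhba by 0.27 and Gbx2 by 0.32. Smaller differences were those of Meis1 (0.01), Tert (-0.02), Jund (-0.10) and Casp8 (-0.11, SE 0.49). Differences of Igf2 (-0.62, SE 0.66), Gas1 (-0.97, SE 1.48) and Igfbp2 (-0.31, SE 1.66) were within their SE. These SEs count the difference by replicate number as spread, so they do not show that the groups were alike.

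The menin complex list (18 measured, 8 higher, 10 lower, median -0.03, adjusted p = 0.860) included Ncoa6 at 0.49 (SE 0.17), Ogt at -0.38 (SE 0.20) and Hcfc1 at 0.23 (SE 0.18). Of 36 measured Hox, Meis and Pbx genes, 16 were higher and 20 lower (median -0.06, adjusted p = 0.798), with Hoxb3 at 0.62 (SE 0.27) and Hoxc5 at 38.6 and 19.5 with Men1 against 10.5 and 17.1, where 3 of the 4 signals were below the controls.

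Proliferation genes did not pass either. Of 49 cell cycle genes 23 were higher and 26 lower (median -0.0061, adjusted p = 0.779), with the proliferation marker Mki67 at 0.31 (SE 0.18) and cyclin Ccne1 at -0.44 (SE 0.19). Of 20 cyclin-dependent kinase inhibitors and p53 targets 6 were higher and 14 lower (median -0.11, adjusted p = 0.711), including Cdkn2d at -0.39 (SE 0.27) and Btg2 at -0.25 (SE 0.20). Of 11 replication histone genes 4 were higher and 7 lower (median -0.02, adjusted p = 0.966).

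Among matrix and signalling lists, the collagen list had 24 genes higher and 25 lower (median -0.03, adjusted p = 0.895), with Matn4 at 0.58 (SE 0.19), Col11a1 at -0.51 (SE 0.20) and Col3a1 at -0.63 (SE 0.48). Matrix remodelling had 12 higher and 14 lower (median -0.01, adjusted p = 0.966). Its members Serpinf1, Plat and Timp1 differed by 0.96 (SE 0.32), -0.50 (SE 0.18) and 0.38 (SE 0.21). A second, dimmer Serpinf1 probe set differed by -0.41 (SE 0.36). For TGF-beta and BMP genes 22 were higher and 11 lower (median 0.06, adjusted p = 0.411), with the BMP antagonist Grem1 at 1.05 (SE 0.43), Id2 at 0.49 (SE 0.19) and Tgfb1 at 0.52 (SE 0.28). Hedgehog genes were 4 higher and 6 lower (median -0.10, adjusted p = 0.711). Wnt genes were 17 higher and 19 lower (median -0.0070, adjusted p = 0.798), with Ryk at -0.40 (SE 0.20). Growth factors and receptors were 26 higher and 22 lower (median 0.02, adjusted p = 0.966), with Fgfr2 at -0.37 (SE 0.19).

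Of 32 immediate-early genes 21 were higher, with a median of 0.18 and an adjusted p of 0.173 in camera at the preset correlation (0.0778 with fry). Myc differed by 0.64 (SE 0.28), Maff by 0.33 (SE 0.17), Klf10 by 0.31 (SE 0.17) and Gadd45b by -0.49 (SE 0.19). Interferon response genes were 15 higher and 19 lower (median -0.04, adjusted p = 0.711), with Ifitm3 at -0.96 (SE 0.24) and Tap1 at -0.42 (SE 0.22). Inflammatory genes were 19 higher and 23 lower (median -0.01, adjusted p = 0.966), with Nfkbie at 0.48 (SE 0.18). In that list, 1 member not named here was lower at an unadjusted limma p under 0.05.

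Of 54 genes of oxidative phosphorylation 17 were higher and 37 lower (median -0.10, adjusted p = 0.342), with Cox5b at -0.24 (SE 0.17). Cytosolic ribosomal protein genes were 7 higher and 24 lower (median -0.07, adjusted p = 0.704), with Rpl6 at -0.23 (SE 0.18). Genes of the unfolded protein response and amino acid metabolism were 29 higher and 13 lower (median 0.10, adjusted p = 0.411). Named members were Cebpb at 0.44 (SE 0.17) and Mthfd2 at 0.43 (SE 0.31), while 1 member not named here was lower at an unadjusted limma p under 0.05. Glycolysis and hypoxia genes were 19 higher and 14 lower (median 0.04, adjusted p = 0.966), with Ndrg1 at -0.31 (SE 0.20). NRF2 targets were 13 higher and 24 lower (median -0.04, adjusted p = 0.829), with Hmox1 at 0.39 (SE 0.17) and Sod3 at -0.996 (SE 0.45).

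No marker list passed. Skeletal muscle markers were 6 higher and 16 lower (median -0.06, adjusted p = 0.342), with Tnni1 at -0.57 (SE 0.18). Fibroblast markers were 10 higher and 12 lower (median -0.02, adjusted p = 0.711), with S100a4 at -0.31 (SE 0.24). Smooth muscle markers were 3 higher and 12 lower (median -0.12, adjusted p = 0.711), with Tpm2 at -0.20 (SE 0.21). Bone and cartilage markers were 6 higher and 11 lower (median -0.06, adjusted p = 0.704), with Sparc at -0.30 (SE 0.18) and Dlx3, at control level with vector, at least 1.60-fold higher with Men1. Medians were 0.03 for adipocyte markers (8 higher, 6 lower, adjusted p = 0.895), -0.05 for epithelial markers (6 higher, 13 lower, adjusted p = 0.711) and 0.04 for endothelial markers (7 higher, 5 lower, adjusted p = 0.711). They were -0.0015 for blood cell markers (10 higher, 12 lower, adjusted p = 0.711) and -0.12 for neural markers (7 higher, 14 lower, adjusted p = 0.704). Krt19, Pecam1 and Cd74 differed by 0.56, 0.41 and 0.27, and Lpl, at control level with Men1, read 25.8 and 23.5 against 27.6 and 45.8. The median, the mean and the camera direction differed in sign in 8 lists: menin complex, cell cycle, matrix remodelling, Wnt, growth factors, inflammatory, glycolysis and blood cell markers.

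**Figure D2:**
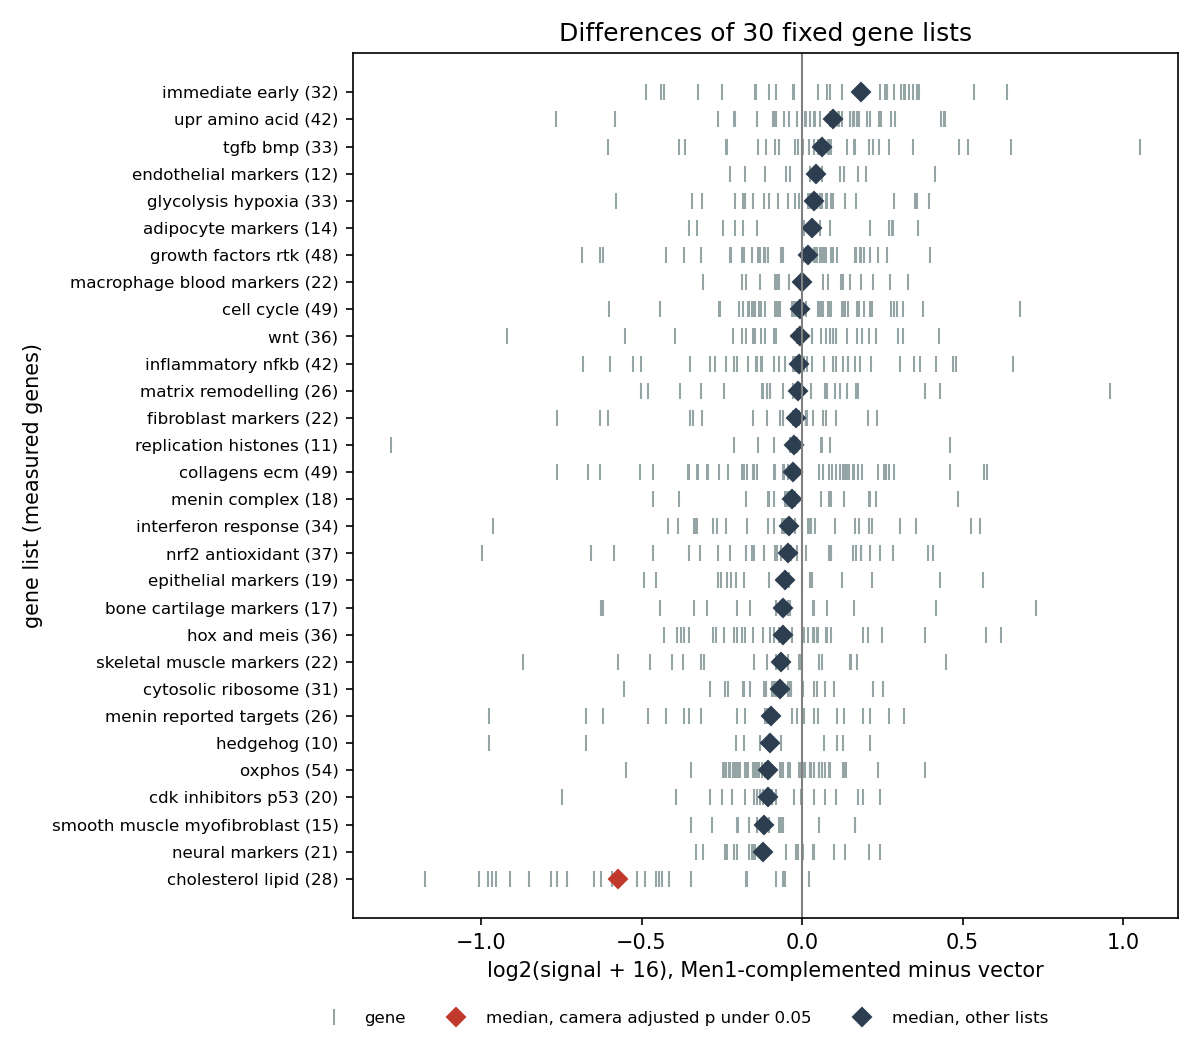
Log2 differences, Men1-complemented minus vector, of the measured genes (ticks) and their median (diamonds) in each of 30 gene lists, with the number of measured genes in brackets. The cholesterol and fatty acid list lies at a median of -0.57, and the other medians lie between -0.12 and 0.18.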

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

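Inclusion of the control probe sets and the cholesterol list restricted to synthesis enzymes were chosen after the data were seen, and the other settings before. By limma, 0 probe sets passed in each setting, with 109 to 1031 at an unadjusted p under 0.05, against 233 as reported and 621 by chance, which was exceeded only without vector replicate 1. With an unadjusted p under 0.01 and an absolute log2 difference of at least 1, in place of the adjusted p, 8 probe sets were taken. The lowest adjusted p over settings was 0.576, without vector replicate 1. Without single arrays the counts at an unadjusted p under 0.05 were 121 and 131 (Men1-complemented replicates 1 and 2 left out) and 1031 and 559 (vector replicates 1 and 2 left out). The lone array of a group was then assumed to vary like the others.

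The cholesterol and fatty acid list kept its direction in all settings run, and passed in camera at the preset correlation in each. Its median was -0.55 with quantile normalization, -0.68 with a pseudocount of 1, and -0.64 to -0.49 without single arrays. With an estimated correlation (adjusted p = 0.227) and with fry (adjusted p = 0.0778), at the same median of -0.57, it did not pass, so 0 lists were called in both. With a pseudocount of 1, fry called 1 list, immediate-early genes (adjusted p = 0.00455), which did not pass in camera at the preset correlation (adjusted p = 0.201), and 0 lists passed with an estimated correlation. Restricted to its 24 enzymes, the cholesterol list had a median of -0.58 and passed in camera at the preset correlation (adjusted p = 6.27e-24) and with fry (adjusted p = 0.0203), but not with an estimated correlation (adjusted p = 0.221). Without single arrays, 1 to 2 lists were called. The additions were the unfolded protein response without vector replicate 1 (adjusted p = 0.00948) and oxidative phosphorylation without vector replicate 2 (adjusted p = 0.0197). With an estimated correlation the adjusted p of these was 0.930 and 0.951, and with fry 0.249 and 0.731. Such fits leave fewer residual degrees of freedom than the main fit, so not passing with an estimated correlation decides nothing. The cause was not tested.

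The labels do not say that equal replicate numbers pair the arrays, and 2 pairs are too few to establish it. Deviations of same-numbered arrays from their group means correlated at 0.258 across probe sets, and at 0.408 across the 4423 with a mean log2 signal above 7. With the replicate block 0 probe sets passed, and 297 were at an unadjusted p under 0.05. The cholesterol list had a camera adjusted p of 4.18e-23 at the preset correlation. With an estimated correlation it was 0.965 (unadjusted p = 0.0549). The block leaves fewer residual degrees of freedom than the main fit, so not passing there decides nothing.

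Men1 ranged from -0.31 to 0.10 without single arrays, and turned without vector replicate 2. Of 115 named genes 24 reversed in at least 1 setting, and 20 of 30 lists did. None of these had passed. Leaving out vector replicate 2 turned the most, 16 genes and 17 lists. Reversals in other settings were Tert (0.0089), cell cycle (0.0081) and Wnt (0.014) with quantile normalization, Wnt (0.012) with a pseudocount of 1, and blood cell markers (0.0076) with the mean of all probe sets. Without dim probe sets they were matrix remodelling (0.014), inflammatory (0.034), fibroblast (0.012), adipocyte (-0.16) and endothelial (-0.027) lists. Of the 91 genes that never reversed, 41 moved by over 1.5 times without a single array. Their values nearest 0 follow by the array left out. For the 21 without vector replicate 2 these were Myc 0.29, Tgfb1 0.17, Mthfd2 0.13, Hoxb3 0.33, Hoxa9 -0.054, Hoxc8 -0.021, Lox -0.23, Gli1 -0.43, Meis2 -0.098, Fgf9 -0.061, Ogt -0.22, Tap1 -0.22, Rpl6 -0.14, Ryk -0.26, Fgfr2 -0.24, Tpm2 -0.030, Lpl -0.10, Abca1 -0.050, Fads1 -0.055, Mvk -0.11 and Tm7sf2 -0.27. For the 10 without Men1-complemented replicate 1 they were Hoxc5 0.26, Hcfc1 0.13, Mki67 0.21, Timp1 0.22, Gli3 0.067, Btg2 -0.11, S100a4 -0.044, Sod3 -0.51, Hmgcs1 -0.48 and Abcg1 -0.39. For the 7 without Men1-complemented replicate 2 they were Cdkn2d -0.061, Ptch1 0.11, Krt19 0.36, Serpinf1 0.54, Scd1 -0.56, Sc5d -0.16 and Ebp -0.053. For the 3 without vector replicate 1 they were Grem1 0.56, Pecam1 0.18 and Ndrg1 -0.15. Of the 10 lists that never reversed, 9 moved as much, with ranges of -0.10 to -0.032 for oxidative phosphorylation, -0.10 to -0.014 for ribosome, 0.012 to 0.17 for TGF-beta and BMP, 0.10 to 0.17 for immediate-early, 0.0026 to 0.030 for growth factors and -0.11 to -0.044 for cyclin-dependent kinase inhibitors. Marker lists among these ranged from -0.17 to -0.070 for bone and cartilage, -0.16 to -0.00019 for epithelium and -0.094 to -0.0064 for skeletal muscle. Other settings could move a list further, since without dim probe sets the skeletal muscle median was -0.18. Ranges without single arrays follow for the results that reversed there, and the cause was not tested. Gene ranges were Cdkn1b -0.10 to 0.17, Cdkn2c -0.38 to 0.19, Jund -0.43 to 0.23, Gas1 -3.01 to 1.06, Fasn -0.17 to 0.058 and Srebf1 -0.15 to 0.034. Those of further genes were Inhba -0.038 to 0.58, Gbx2 -0.083 to 0.72, Igf2 -1.44 to 0.20, Hoxc6 -0.48 to 0.070, Bmi1 -0.12 to 0.49 and Ezh2 -0.0058 to 0.27. Next came Ptn -1.19 to 0.35, Casp8 -0.63 to 0.41, Igfbp2 -2.41 to 1.78, Foxa2 -0.086 to 0.022, Tert -0.28 to 0.24 and Meis1 -0.21 to 0.22. The last were Pparg -0.30 to 0.32, Col3a1 -1.29 to 0.031, Lpin1 -1.22 to 0.087, Me1 -0.36 to 0.0052, Acly -0.41 to 0.063 and Insig1 -0.051 to 0.095. List medians ranged as follows, for menin targets -0.21 to 0.054, menin complex -0.11 to 0.12, Hox and Meis -0.14 to 0.040, cell cycle -0.035 to 0.052, histones -0.10 to 0.024 and collagens -0.19 to 0.058. Further lists were matrix remodelling -0.19 to 0.067, hedgehog -0.20 to 0.14, Wnt -0.17 to 0.16, interferon -0.23 to 0.13, inflammatory -0.069 to 0.078 and glycolysis -0.11 to 0.077. Others were unfolded protein response -0.030 to 0.13, NRF2 -0.10 to 0.047, fibroblast -0.26 to 0.15, smooth muscle -0.28 to 0.11, adipocyte -0.14 to 0.14 and endothelial -0.062 to 0.10. The remaining lists were blood cell -0.081 to 0.18 and neural -0.25 to 0.0022. Among the genes that reversed, Cdkn1b, Ptn and Pparg were at control level with Men1, and Hoxc6, Foxa2 and Insig1 in both groups. Signal over the controls limits dim genes, since 61.9% to 70.7% of probe sets exceeded the highest unspiked control.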

Other observations

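Quantile normalization and the left-out arrays were chosen before the data were examined, and the genes, the ranking among random lists, the tests by replicate number, the exchanged labels, the divisions of the arrays, the comparison with control signal and the branches after. Some genes read differently on the arrays with replicate number 2 than on those with number 1, in the same direction in both groups, although by unequal amounts. Igfbp2, a binding protein of insulin-like growth factors, read 72.1 and 56 on the number 1 arrays (Men1-complemented, then vector) and 682.8 and 1305.3 on the number 2 arrays. Gas1, a hedgehog co-receptor, read 52.8 and 52.5 against 281.9 and 1139.4. The homeobox genes En1 and Shox2 read 90.3 and 73.6 against 384.9 and 451, and 34.3 and 29 against 179.4 and 465.6. Postn, periostin, read 5.7 and 8.2 against 46.4 and 125.1. In the other direction, Cnn1, the smooth muscle protein calponin, read 882.1 and 1547.7 against 217 and 199.9, Rgs16 read 1406.2 and 1356.8 against 326.8 and 240.1, and F3, tissue factor, read 1162.3 and 1562.5 against 417 and 364.6. In a limma fit with the group as a term, 0 probe sets passed for replicate number (smallest adjusted p = 0.340), and 1125 were at an unadjusted p under 0.05. The fibroblast marker list was higher with number 2 in 18 of 22 genes (median 0.21, camera adjusted p = 0.0370). Glycolysis and hypoxia genes were lower in 23 of 33 (median -0.10, adjusted p = 0.0370). Smooth muscle markers were lower in 8 of 15 (median -0.02, adjusted p = 0.0370). With an estimated correlation the camera adjusted p of all 3 lists was 0.987. That fit left fewer residual degrees of freedom than the main fit, so this value decides nothing. Without the group as a term 0 lists passed in camera at the preset correlation (smallest adjusted p = 0.0658). The Hox and Meis (adjusted p = 0.811), collagen (adjusted p = 0.880) and matrix remodelling (adjusted p = 0.880) lists did not pass. Nor did blood cell markers, also higher in 18 of 22 (camera adjusted p = 0.508), or endothelial markers, higher in 11 of 12 (camera adjusted p = 0.680). Such a count was therefore not particular to fibroblast markers. Median signals were also higher on number 2, at 55.65 against 54.3 with Men1 and 62.4 against 50 with vector.

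The lower cholesterol and fatty acid list in the Men1-complemented arrays was set against technical explanations. After quantile normalization its median was -0.55, against -0.57 as reported, and with 1 array left out the median nearest 0 was -0.49, which argues against between-array scaling or a single array as the whole cause. Its percentile among random lists of matched signal was 0, which argues against signal level. An extreme percentile was not particular to this list, since oxidative phosphorylation (median -0.10) was also at 0, immediate-early genes at 100 and the unfolded protein response at 99.7. The difference may reflect Men1, as a hypothesis, but unmeasured differences between cultures, such as sterol supply or density at harvest, stay open because the design confounds them with the groups.

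The Men1 probe set was not higher in the Men1-complemented arrays. Exchanged labels were tried as an explanation, and the largest Men1 difference that any exchange gave was 0.14 (SE 0.20), but no exchange of signals this near the controls gives a large difference, so swapped labels stay open. Beside the highest unspiked control of the same array, Men1 read 18.8 and 22.5 against 25.9 and 27.4 on the Men1-complemented arrays, and 18.1 and 29.5 against 15.9 and 20 on the vector arrays. Whether the probe set reads the introduced sequence therefore cannot be told apart from a low Men1 level, because its signal lies near the controls. No biological explanation was tested.

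The arrays differed more by replicate number than by group, since of the 3 ways to divide them into pairs the labelled groups gave 233 probe sets at an unadjusted p under 0.05, the groups exchanged in 1 number gave 506, and replicate number gave 1491, with 0 past the adjusted threshold in each. After quantile normalization replicate number gave 1448 against 293 for the labelled groups, which argues against scaling. With separately derived cultures as a possible explanation, Hox and Meis genes had the same sign in both groups in 72.2% of members, beside 56.9% of all genes. Controls spiked in at hybridisation were also higher with number 2 in both groups, at a mean log2 of 9.95 and 9.72 (Men1-complemented, then vector) on number 1 and 10.05 and 10.33 on number 2. Among 2913 probe sets as bright, 507 differed beyond the range of these controls in the same direction in both groups and 13 in opposite directions, but 503 of the 507 were lower, where that range ended at -0.14, so cultures cannot be told apart from array handling.

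A hypothesis was that sterol enzymes differed more than fatty acid genes. The mean difference was -0.69 over 16 sterol enzymes and -0.41 over 8 fatty acid genes, such as Fasn and Scd1, and all 24 were lower with Men1. A two-sided exact permutation test across genes gave p = 0.0272, but these genes are regulated together and were measured on the same arrays, so that p decides nothing. Per array, the sterol mean less the fatty acid mean was -1.55 and -1.43 with Men1 and -1.17 and -1.24 with vector. The exact permutation p over the 3 ways to divide the arrays was 0.333, the smallest they can give, so the hypothesis stays open.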
